A study of Mus musculus with 9 samples.

How the data were processed

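Polyadenylated RNA was sequenced from the posterior second heart field (pSHF) of mouse embryos at embryonic stage E10.5. The pSHF is the mesoderm behind the early heart tube that supplies cells to the atria, the atrial septum and the inflow region. The tissue was microdissected from embryos of mixed strain background. The 9 libraries fall into 2 genotypes named in the labels, 4 Shh WT and 5 Shh KO. Shh encodes Sonic hedgehog, a secreted ligand of the Hedgehog pathway. Per the labels' protocols, libraries were made with an Illumina TruSeq RNA kit and read on a HiSeq2500 as stranded single-end reads of 50 bp. The labels do not say that the libraries of a genotype came from separate embryos or litters, so p-values measure only the spread between these samples, which may be technical.

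Per the submitters' processing notes, the reads were handled with TopHat2 2.0.10, a spliced aligner, and Cuffdiff 2.1.1, which estimates expression per gene and tests 2 groups of libraries against each other. Which Cuffdiff options were used, including any strand setting and the scaling between libraries, is not given in the sources used here. The first deposited table holds 27198 rows, each with a position, a log2 fold change, a test statistic, a p-value, a q-value and a yes or no for significance. The second, shorter deposited table holds 253 genes, each with 1 pooled FPKM value per genotype, their log2 ratio and a p-value and q-value. FPKM, named in the file headers, is a count of fragments scaled to transcript length and to the size of the library. The test statistic is the authors' own score from Cuffdiff and was used here only with the fold change to estimate precision. Both tables are comparisons made by the authors. No per-library value was used here, so no standard deviation, no n per value and no other test over libraries could be given. The depth of each library is unknown for the same reason, and it limits how well low genes can be compared.

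Several properties were tested on the tables before use. A p-value under 1 was taken as the sign that Cuffdiff tested a row, since the deposited full table has no status column. Benjamini-Hochberg adjustment over these 16944 rows returned the deposited q-value of all 16944 within 0.0001. The other 10254 rows were treated as untested. The smallest p-value in the table is 5e-05, shared by 153 tested rows, so the smallest q-value is 0.00554 and genes at that q cannot be ranked by it. In the full table, 1190 rows hold a spreadsheet error in place of the log2 fold change, 26 of them tested. A further 26 rows carry symbols that a spreadsheet turned into dates, and 392 rows hold several symbols. The deposited fold change and the deposited statistic have opposite signs in all 16918 tested rows where both are numeric. The fold change was read as Shh KO over Shh WT, because it equals the log2 ratio of the pooled FPKM values of the shorter table to within 1.07e-05 for its 253 genes. Of the tested rows, 3879 (22.9%) have no gene name. They were left out of gene counts and lists, which leaves 13065 named tested rows, 13048 of them with a numeric fold change.

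The submitters' processing notes name the build mm9. The positions in the full table were compared with RefSeq genes of GRCm38 (mm10): of 20524 symbols found in both, 99.5% overlapped their GRCm38 gene. Positions are therefore given as mm10. The deposited starts count from 0, since adding 1 gave a GRCm38 gene start for 47.6% of these symbols against 2.84% without it, and printed starts have 1 added. Biotypes and neighbouring genes are from the same RefSeq table.

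A gene was called at a Cuffdiff q under 0.05, as deposited, and higher or lower by the sign of its fold change. Before the data were examined, 26 gene lists were fixed from textbook knowledge of the tissue. They are Hedgehog pathway genes, mesodermal genes known to respond to Hedgehog, second heart field progenitor genes, cardiac transcription factors, cardiomyocyte differentiation genes, smooth muscle genes and skeletal myogenic genes. Markers of endothelial, erythroid, foregut endoderm, neural crest and autonomic, neural tube, sclerotome, epicardial, hepatoblast and macrophage cells were fixed as well. The remaining lists hold anterior Hox genes, FGF, BMP, Wnt and retinoic acid response genes, proliferation, p53, hypoxia, immediate early and sex chromosome genes. For each list the called members were counted, also with the p-values adjusted over the list alone. Called members were set against all other named tested rows with a numeric fold change by Fisher's exact test, two-sided. Its p-values were adjusted by Benjamini-Hochberg over 52 tests (26 lists, 2 directions). The median log2 fold change of each list was placed among the medians of 10000 random lists of the same size (percentile), as a description of these libraries. Genes are not replicates, so both tests compare genes within the same 9 libraries.

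Some parts of the plan assumed FPKM values for every gene. The full table as used here has none, so list medians use the deposited log2 fold change without a pseudocount. Random lists were matched in 20 bins on the size of the fold change divided by the statistic, a measure of precision, in place of mean expression. Across the called genes, which are not independent replicates, this measure had a Spearman correlation of −0.708 with the log2 mean FPKM. Centring used the median of all named tested rows. A filter at 1 FPKM with new adjustment, the same filter on list members and background, and pseudocounts for lists were not run.

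The genes named in the text follow a rule fixed in advance. They are the 10 largest rises and falls among called genes with at least 1 FPKM in the higher genotype, the 5 called genes of highest mean FPKM in each direction, and members of the lists. Shh, Gli1, Ptch1, Hhip and Foxf1 were always named. Some genes that meet the rule are not reported here. Alternatives covered q thresholds, minimum folds, Benjamini-Yekutieli adjustment, centring, pseudocounts for single genes and the removal of rows that overlap others. The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data with 13048 rows drawn for the comparison of Shh KO with Shh WT. There, 55% of 100 rows changed 2-fold and 87% of 100 rows changed 4-fold were called, and 2.74% of the calls were rows without a change. A shifted list of 20 genes reached percentile 100, and 2.5% of 200 unshifted lists fell outside the central 95% of random lists. The simulated rows were drawn independently, whereas members of a real list can move together. The simulation therefore does not calibrate the percentiles of the real lists, of which 14 of 26 lay outside the central 95%.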

Results

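Gene expression was measured by polyA RNA-seq in pSHF tissue of 4 Shh WT and 5 Shh KO libraries at embryonic stage E10.5. The series concerns gene networks that depend on Hedgehog signalling in cardiac progenitors, and the comparison asks which transcripts of the pSHF differ when Shh is lost. All expression values, fold changes and Cuffdiff q-values below come from the authors' deposited tables, which hold 1 pooled value per genotype without replicate values. Depth per library is unknown. Fold changes are Shh KO over Shh WT.

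The Shh KO dissections had lower transcripts of several Hedgehog pathway genes and mesodermal genes that respond to Hedgehog, and higher transcripts of many cardiomyocyte genes and of hepatoblast genes. Macrophage and epicardial markers moved with them, with median log2 fold changes of 1.01 and 0.46. In the authors' deposited table, Hhip, a membrane protein that binds and limits Hedgehog ligand, dropped from 2.98 to 0.209 FPKM. Foxf2, a forkhead transcription factor of mesoderm near the gut, dropped from 22.0 to 3.17 FPKM in the authors' deposited table. In the same comparison, Nppa, the atrial natriuretic peptide gene of heart muscle, rose 7.71-fold to 65.9 FPKM in the authors' deposited table. Cuffdiff called 203 named genes higher and 50 lower in Shh KO at q under 0.05, so 80.2% of the 253 calls were rises.

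The Shh row itself was the first check of the labels. In the authors' deposited table it read 15.7 FPKM in Shh WT and 5.44 FPKM in Shh KO, a log2 fold change of −1.53 (Cuffdiff q = 0.00554). This row lies on chromosome 5 (28456840 to 28719209, mm10) and is wider than Shh (28456840 to 28467101), since it also spans the long noncoding RNA gene 9530036O11Rik and the pseudogene Gm10290. A wide span alone does not show that reads of the neighbours entered the Shh value. Hoxa4 (0.16), Hoxa5 (0.64) and Hoxa6 (1.27) share a span but differ in log2 fold change in the authors' deposited table. The labels do not state which part of Shh was removed, so the source of the remaining 34.6% cannot be assigned. The same q was reached by Ptch1, Gli1 and Hhip. Ptch1, the Hedgehog receptor (chromosome 13, 63508333 to 63565520), went from 33.8 to 11.6 FPKM in the authors' deposited table. Gli1, a transcription factor induced by the pathway, went from 38.2 to 15.0 FPKM there, in a row that overlaps Arhgap9.

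Of 16 tested Hedgehog pathway genes, 5 were called lower, among them Shh, Ptch1, Gli1 and Hhip, and 1 higher, against 5 lower and 3 higher when adjusted over the list alone. The gene called higher was Gas1, a membrane protein that binds Hedgehog ligand, at a log2 fold change of 0.60 in the authors' deposited table (Cuffdiff q = 0.0454). Gli2 (−0.33), Gli3 (−0.20), Smo (−0.23) and Sufu (−0.19), which act downstream of the receptor, were not called in the authors' deposited table (log2 fold changes). The calls lower exceeded those among other genes (Fisher's exact test, adjusted p = 3.7e-08). Shh is 1 of the 5, and the genotype by itself may give its fall, so Shh adds no evidence about the pathway. It also counts in the list's median, and no test without Shh alone was run. The list's median of −0.19 lay at percentile 0.01 of random lists. Leaving out rows that overlap others removes Shh and Gli1 and leaves 3 members lower, an alternative chosen after seeing the data.

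Mesodermal genes known to respond to Hedgehog formed the list with the most falls. Of 20 tested members, 9 were called lower and 0 higher, against 9 lower and 1 higher when adjusted over the list alone (Fisher's exact test, adjusted p = 3.52e-16). The list's median log2 fold change was −0.58, at percentile 0 of random lists. Foxf2 (chromosome 13, 31625724 to 31632586) and Foxl1 (chromosome 8, 121127685 to 121130644) had log2 fold changes of −2.80 and −2.47 in the authors' deposited table. Foxf1, on chromosome 8 at 121084386 to 121088154, had 83.5 FPKM in Shh WT and 42.5 FPKM in Shh KO in the authors' deposited table. Foxd2, Foxd1 and Foxc1 had log2 fold changes of −1.57, −1.01 and −0.76 in that deposited table. Osr1, a zinc finger factor of the pSHF and intermediate mesoderm, went from 71.4 to 33.5 FPKM in the authors' deposited table (chromosome 12, 9574442 to 9581500). Wnt2b, a Wnt ligand, and Hsd11b2, an enzyme that inactivates glucocorticoids, had log2 fold changes of −0.90 and −0.75 there. At a Cuffdiff q under 0.01, 5 members remained lower. In the same libraries hepatoblast, macrophage and epicardial markers had medians above 0, given with their lists.

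**Figure D1:**
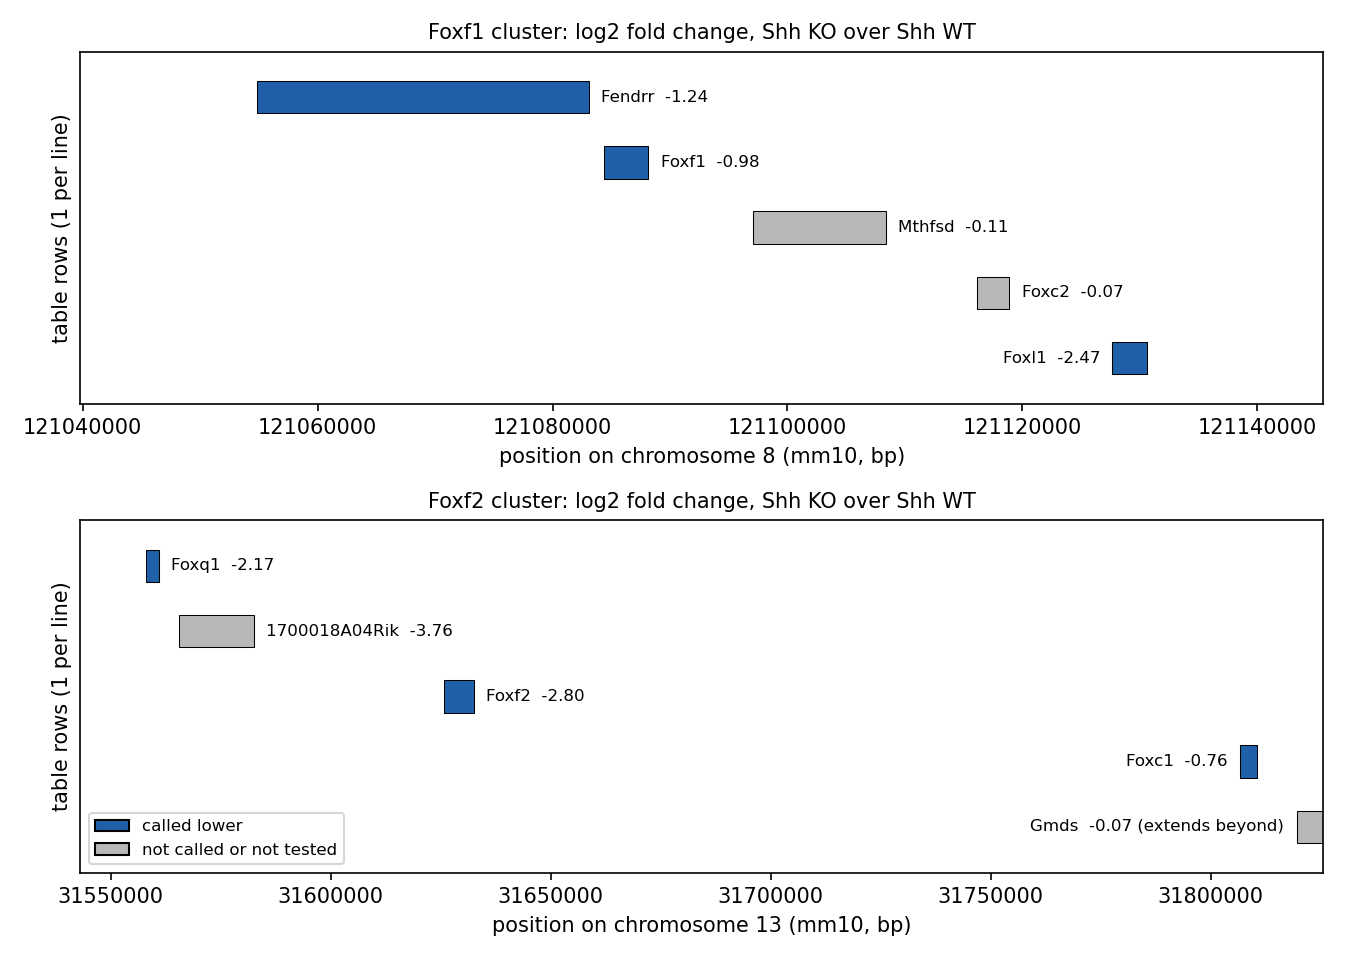
Maps of the Foxf1 cluster on chromosome 8 and the Foxf2 cluster on chromosome 13 (mm10), with position in bp along the horizontal axis, 1 gene per line, blue boxes for genes called lower and grey for genes not called, and the log2 fold change from the authors' deposited table beside each name. Foxl1 at −2.47 and Foxf2 at −2.80 are blue, while Foxc2 and Gmds, both at −0.07, are grey.

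Falls were uneven inside the clusters of forkhead genes. On chromosome 8, the noncoding gene Fendrr (−1.24, 121054806 to 121083091) and Foxf1 (−0.98) were called lower in the authors' deposited table. Between Foxf1 and Foxl1, Mthfsd (−0.11) and Foxc2 (−0.07) were not called in the authors' deposited table. On chromosome 13, Foxq1 (−2.17), Foxf2 and Foxc1 were called lower in the authors' deposited table, while Gmds (−0.07) and the noncoding 1700018A04Rik (−3.76, Cuffdiff q = 0.669) were not. Fendrr, Mthfsd, Gmds and 1700018A04Rik were chosen for their position after their values were seen.

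Second heart field progenitor genes gave 2 calls lower and 0 higher among 20 tested, and the same counts when adjusted over the list alone (Fisher's exact test, adjusted p = 0.017). With calls at a Cuffdiff q under 0.01 the list no longer passed (1 lower, Fisher's exact test, adjusted p = 0.272). These were Osr1 and Tbx1, a T-box factor of pharyngeal and second heart field mesoderm, which went from 44.2 to 22.7 FPKM in the authors' deposited table (Cuffdiff q = 0.0437). Isl1 (−0.39), Mef2c (−0.10), Nkx2-5 (−0.06) and Fgf8 (−1.07, q = 0.47) were not called by Cuffdiff in the authors' deposited table. The median of −0.04 lay at percentile 19.7.

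The remaining large falls outside these lists included a row shared by Mir22 and its host gene Mir22hg, at −3.22 on the log2 scale in the authors' deposited table. Agtr2, an angiotensin receptor (−2.61), Neto1 (−2.47) and Dleu7 (−1.84) were also called lower in the authors' deposited table. With 1 FPKM added to both pooled values, the log2 fold changes of low genes shrank to −0.86 for Agtr2, −0.78 for Neto1, −1.09 for Dleu7, −0.86 for Foxq1 and −1.72 for Hhip. Snai1, a zinc finger factor of mesenchymal cells, went from 65.8 to 36.4 FPKM in the authors' deposited table.

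Cardiomyocyte differentiation genes formed the list with the most rises. Of 29 tested members, 16 were called higher and 0 lower, against 20 higher and 0 lower when adjusted over the list alone (Fisher's exact test, adjusted p = 1.92e-20). The median log2 fold change was 1.06, at percentile 100 of random lists, and 28 of the 29 had a positive fold change. Myl7, the atrial myosin light chain, went from 437 to 999 FPKM and was the called gene of highest mean level in the authors' deposited table. Myl4 went from 256 to 654 FPKM and Actc1, the cardiac actin, from 261 to 518 FPKM in the authors' deposited table. Nppa (2.95, chromosome 4, 148000746 to 148002067), Cox6a2 (2.23), Myl3 (2.07) and Myl2 (1.96) had the largest called log2 fold changes of the list in the authors' deposited table. Actn2 (1.32), Ldb3 (1.25) and Tnnt2 (1.06) were also called in the authors' deposited table, as was Tnni3, which went from 29.5 to 83.5 FPKM. Myh6 and Myh7 share 1 row of the table (0.78). Members not called in the authors' deposited table included Tpm1 (0.36), Ryr2 (0.23), Atp2a2 (0.16) and Gja5 (−0.15). In the same comparison, hepatoblast, macrophage and epicardial markers had medians of 1.77, 1.01 and 0.46.

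**Figure D2:**
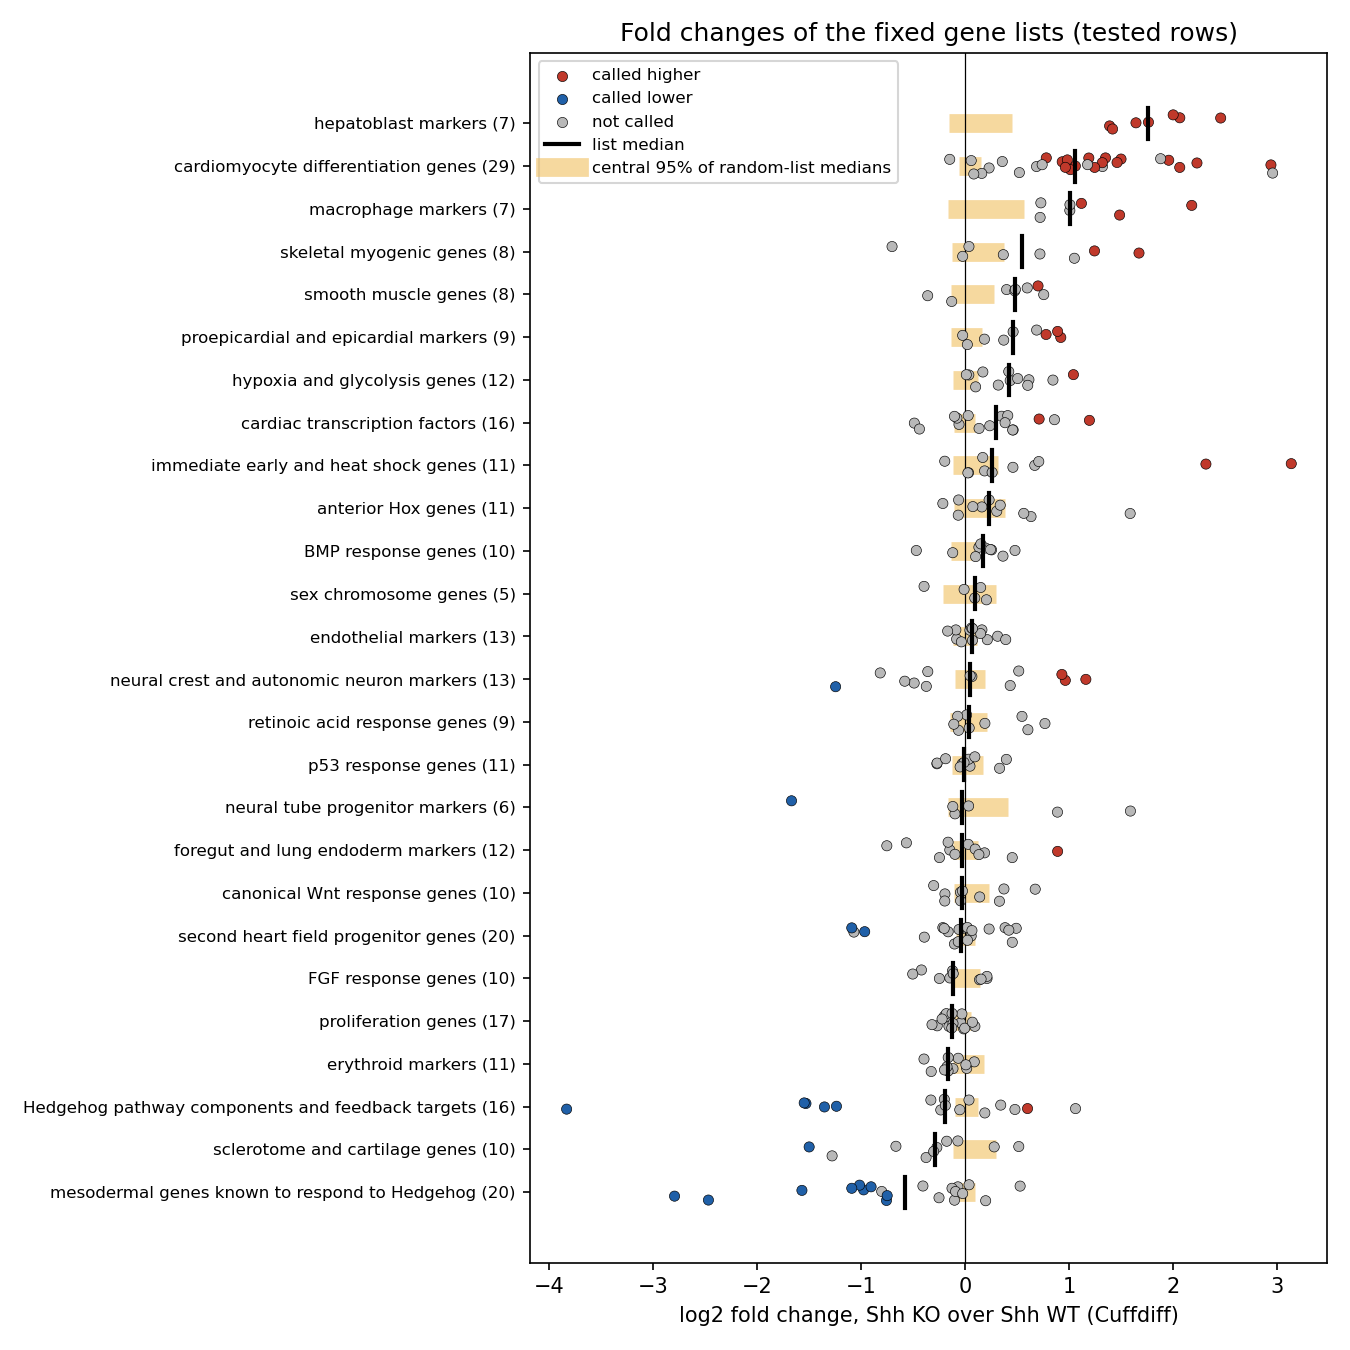
Log2 fold changes (Shh KO over Shh WT, horizontal axis) of the tested members of the 26 gene lists, from the authors' deposited table, with 1 point per gene (red called higher, blue called lower, grey not called), a black bar at each list's median and a shaded band for the central 95% of matched random-list medians. Cardiomyocyte (median 1.06) and hepatoblast (1.77) lists lie to the right of their random lists, and mesodermal Hedgehog response genes (−0.58) lie to the left.

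Among 16 cardiac transcription factors tested, 2 were called higher and 0 lower, against 3 higher and 0 lower when adjusted over the list alone. Hand1 was among them, at a log2 fold change of 1.20 in the authors' deposited table. Of the 16, 11 had a positive fold change, while Gata5 (−0.49) and Tbx5 (−0.44) went the other way without a call in the authors' deposited table. The number of calls did not pass the test against other genes (Fisher's exact test, adjusted p = 0.109) but passed with calls at a q under 0.10 (3 higher, adjusted p = 0.0233), while the median of 0.30 lay at percentile 100. For smooth muscle genes, 1 of 8 tested was called, Acta2 at 0.70 in the authors' deposited table, with 2 higher when adjusted over the list alone (median 0.48, percentile 99.9, Fisher's exact test, adjusted p = 0.409). For skeletal myogenic genes, 2 of 8 were called higher, against 4 higher and 1 lower when adjusted over the list alone (median 0.55, percentile 99.7, Fisher's exact test, adjusted p = 0.0366). They were Acta1 (1.25), also transcribed in embryonic heart, and Pitx1 (1.68), a homeobox factor of hindlimb and pharyngeal arch, in the authors' deposited table. Neither is specific to skeletal muscle progenitors, and Myod1 stood at 0.04 in the authors' deposited table.

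Hepatoblast markers were all called higher, 7 of 7 tested, also when adjusted over the list alone (Fisher's exact test, adjusted p = 3.45e-12). Afp, alpha-fetoprotein, went from 95.6 to 325 FPKM in the authors' deposited table. Apoa1 went from 12.5 to 69.1 FPKM and Alb, albumin, from 6.11 to 25.6 FPKM in the authors' deposited table. Ttr (1.65), Fgb (1.42), the liver factor Hnf4a (1.39) and Serpina1a completed the called members in the authors' deposited table. The median of 1.77 lay at percentile 100.

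Markers of other cells that the dissection could hold moved in different ways. Macrophage markers gave 3 calls higher among 7 tested and 6 when adjusted over the list alone (median 1.01, percentile 99.9, Fisher's exact test, adjusted p = 0.00129). Tyrobp (2.18), Fcer1g (1.49) and C1qb (1.12) were these members in the authors' deposited table. Epicardial markers gave 3 calls higher among 9 and 5 when adjusted over the list alone (median 0.46, percentile 100, Fisher's exact test, adjusted p = 0.00252). With calls at a Cuffdiff q under 0.01, 1 member of each of these lists was higher and neither list passed (Fisher's exact test, adjusted p = 0.325 for macrophage and 0.379 for epicardial markers). Wt1 (0.92), Krt19 (0.89) and Upk3b (0.78), genes of mesothelial cells, were called in the authors' deposited table. Endothelial markers gave 0 calls among 13 with Cuffdiff, also when adjusted over the list alone, with a median of 0.07 (percentile 88.1) and 1 member at an unadjusted p under 0.05. Erythroid markers gave 0 among 11 by both adjustments, with a median of −0.16 (percentile 0.655) and 0 members at an unadjusted p under 0.05. Krt19 was the 1 call among 12 foregut endoderm markers, against 1 higher and 1 lower (Nkx2-1, −0.75) when adjusted over the list alone (median −0.03, percentile 25.7, Fisher's exact test, adjusted p = 0.525).

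Neural markers went both ways. Of 13 neural crest and autonomic markers tested, 3 were called higher and 1 lower, against 3 and 2 when adjusted over the list alone (median 0.05, percentile 54.2). The pan-neuronal genes Elavl3 (1.16), Tubb3 (0.97) and Stmn2 (0.93) were higher in the authors' deposited table (Fisher's exact test, adjusted p = 0.00703, and 0.0547 with calls at a q under 0.01). Ret, a receptor of enteric neural crest, was lower at −1.25 in the authors' deposited table (Fisher's exact test for lower calls, adjusted p = 0.181, and 0.0135 with 2 calls at a q under 0.10). Among 6 tested neural tube markers, 1 was called, Nkx6-1 at −1.67 in the authors' deposited table, against 2 higher (Sox3 and Pax6) and 1 lower when adjusted over the list alone (median −0.03, percentile 17.7, Fisher's exact test, adjusted p = 0.108). Of 10 sclerotome genes, 1 was called lower, against 2 when adjusted over the list alone (median −0.29, percentile 0.01, Fisher's exact test, adjusted p = 0.151).

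The 10 largest called rises included Nppa and Fosb, given with their lists. Robo3, an axon guidance receptor, went from 0.0683 to 1.49 FPKM in the authors' deposited table. Sst, the somatostatin gene, went from 0.927 to 14.7 FPKM and Hmx1 from 1.63 to 15.1 FPKM in the authors' deposited table. Hoxb9 rose from 0.948 to 10.3 FPKM and Hoxc8 from 0.214 to 2.32 FPKM in the authors' deposited table. Prdm12 (2.94) and Pou4f1 (2.83), factors of sensory neurons, and the glutamate receptor gene Grm2 (2.79) were close behind in the authors' deposited table. The ratios of low genes depend on the scale: with 1 FPKM added to both pooled values, the log2 fold changes were 1.22 for Robo3, 1.45 for Hoxc8, 1.27 for Prdm12, 1.06 for Pou4f1, 1.18 for Grm2 and 0.95 for Fosb. Among abundant genes, Col1a1 (163 to 281 FPKM) and Lars2 (199 to 300 FPKM) were also called higher in the authors' deposited table.

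**Figure D3:**
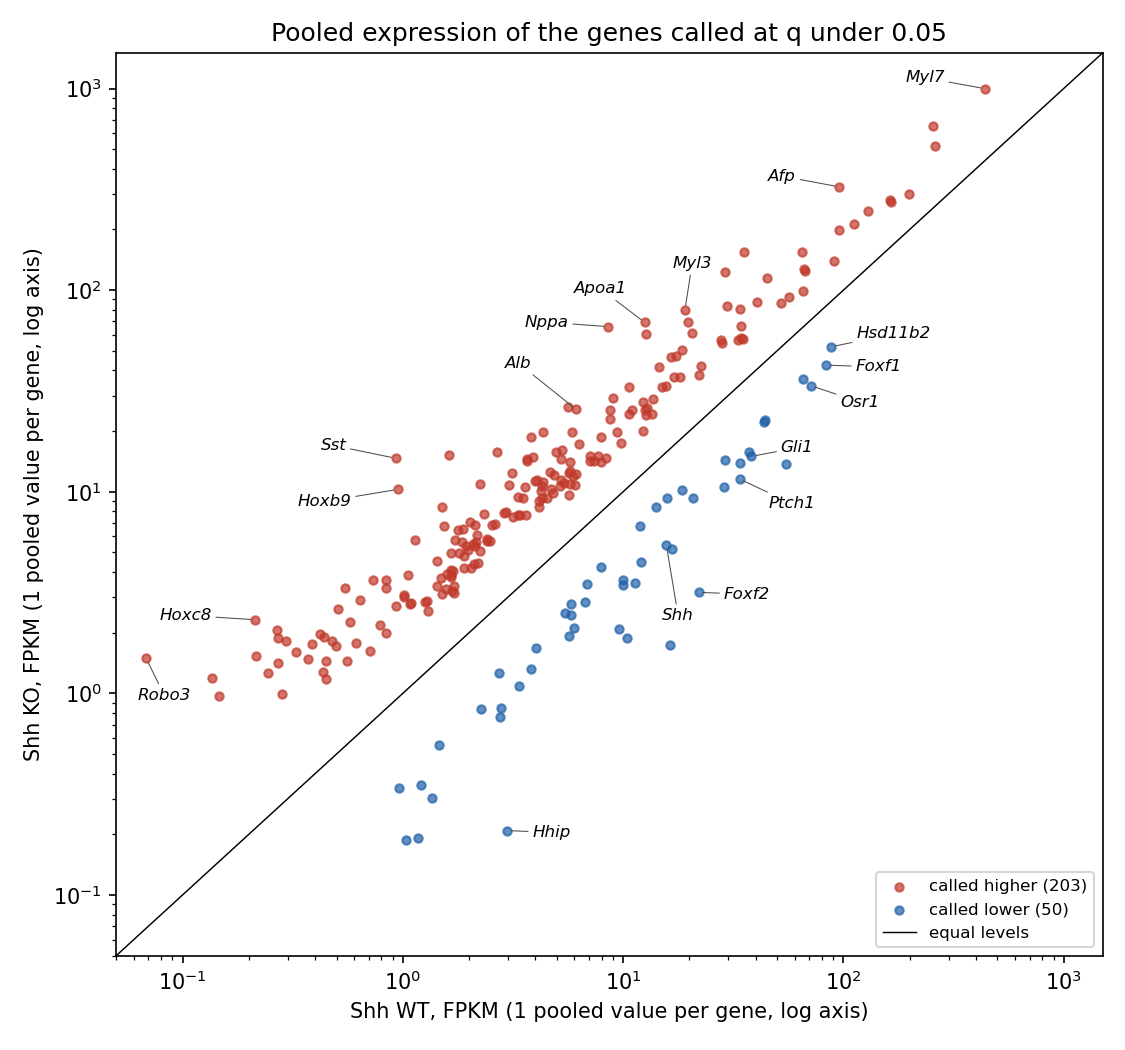
Pooled FPKM of the 253 called genes in Shh WT (horizontal log axis) and Shh KO (vertical log axis) from the authors' deposited table, 1 point per gene, with the line of equal levels. The 203 genes called higher lie above the line up to Myl7 at 999 FPKM, and the 50 called lower lie below it with Hhip at 0.209 FPKM in Shh KO.

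Signalling and cell state lists gave few calls. No member was called by Cuffdiff, over all genes or adjusted over the list alone, among 10 FGF (median −0.12, percentile 3.37), 10 BMP (0.17, percentile 99.6) and 10 Wnt (−0.03, percentile 15) response genes. The same held for 9 retinoic acid response genes (median 0.04, percentile 58.9) and 11 anterior Hox genes (0.23, percentile 85.5). It also held for 17 proliferation genes (−0.13, percentile 1), 11 p53 response genes (−0.01, percentile 33.2) and 5 sex chromosome genes (0.09, percentile 67.4). At an unadjusted Cuffdiff p under 0.05 there was 1 member each of the FGF, BMP and Wnt lists, 2 each of the retinoic acid and Hox lists, and 0 of the other lists just named. Hypoxia and glycolysis genes had 1 call among 12, Adm at 1.04 in the authors' deposited table, 3 when adjusted over the list alone, and a median of 0.43 at percentile 100 (Fisher's exact test, adjusted p = 0.525). Immediate early and heat shock genes had 2 calls among 11, also when adjusted over the list alone (median 0.26, percentile 95.2, Fisher's exact test, adjusted p = 0.0628, and 0.0456 with calls at a q under 0.01). These were Fosb (3.14) and Fos (2.32) in the authors' deposited table, transcription factor genes induced quickly by stimulation. Medians and means differed in sign for neural tube, Wnt and p53 genes, whose means were 0.11, 0.07 and 0.01.

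The 253 calls were the 253 genes of the authors' shorter deposited table, all in the same direction. Of 13048 named tested rows with a numeric fold change, 980 had an unadjusted Cuffdiff p under 0.05, which unchanged genes can also reach. Called rises ranged from 0.59 to 4.45 on the log2 scale and called falls from −0.75 to −3.83 in the authors' deposited tables, with 168 rises and 39 falls of at least 2-fold. The count of rises dropped to 132 at a q under 0.01. Benjamini-Yekutieli adjustment left 0 genes in either direction, since the smallest p of the table gives 0.0571 there.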

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

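The tests in this part were chosen after the values were seen. The comparison left out 13 unnamed loci that Cuffdiff called at q under 0.05 in the authors' deposited table, 6 higher, 3 lower and 4 without a numeric fold change. Of those with a fold change, 7 lay within 10000 bp of a named locus of the same table, and 4 of these had the same call as that locus. By the RefSeq positions, 1 lies inside Ptch1 (log2 fold change −2.22) and 1 inside Paqr9 (1.32), while the others lie 324 bp from Nkx6-1 (−1.99) and 82 bp from Fendrr (−2.36), fold changes from the authors' deposited table.

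Foxe1, a forkhead factor of thyroid and pharyngeal endoderm (chromosome 4, 46344194 to 46345309), was called by Cuffdiff in the authors' deposited table (q = 0.00554), but a spreadsheet error stands in place of its fold change. No direction was inferred, and it is in neither count of called genes.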

How the results depend on the processing

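A pseudocount of 0.1 FPKM moved 18 of the 253 called log2 fold changes by at least 0.25, and 1 FPKM moved 116. Neither a pseudocount nor centring, by 0.025, could turn the direction of a called gene, so both bear on size alone. At a Cuffdiff q under 0.01, 132 genes were called higher, 167 of the genes in the shorter table remained, and 5 mesodermal Hedgehog response genes were lower, as fewer genes pass a stricter threshold. Benjamini-Yekutieli adjustment gave 0 genes higher and 0 lower, because its smallest q was 0.0571, against 980 of 13048 at an unadjusted p under 0.05. Leaving out overlapping or multi-symbol rows left 3 Hedgehog pathway genes lower, since Shh and Gli1 overlap other genes. That last removal, for lists, was chosen after seeing the data, as were adjustment over named genes (224 higher, 56 lower), counting unnamed loci (209 and 53), a minimum of 1 FPKM (201 and 49) and random lists without matching. Among the tests of lists against other genes, the second heart field, macrophage, epicardial and neural crest (higher) lists no longer passed with calls at a q under 0.01, while immediate early genes passed there. Cardiac transcription factors and neural crest markers (lower) passed with calls at a q under 0.10. The other counts of genes called higher ran from 168 (at least 2-fold) to 282 (q under 0.10), and of genes called lower from 35 (q under 0.01) to 69 (q under 0.10). No paired analysis was possible because the tables used here carry no per-library values. Leaving out replicates and other splits of the samples were not run for want of such values. The filter at 1 FPKM with new adjustment or as background, and pseudocounts for lists, were not run because pooled FPKM values were at hand for the called genes only. Depth is unknown, which limits what can be said of genes under about 1 FPKM.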

Other observations

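The tests in this part were chosen after the result was seen, except those on further hepatic and further neuronal genes, whose outcome was stated before their fold changes were examined. The genes and added lists here were also chosen after seeing the data. Among 18 tested Hox genes of paralog groups 5 to 13, 7 were called higher and 1 lower in the authors' deposited table, with a median log2 fold change of 1.05, in a list drawn up after some of the rises were seen. Hoxb8 (2.29), Hoxb7 (1.81) and Hoxc6 (1.72) were higher with Hoxb9 and Hoxc8, while Hoxa10, a more posterior gene, was lower at −1.54 in the authors' deposited table. Hoxd10 (−2.17, Cuffdiff q = 0.0513), Hoxa11 (−1.27), Hoxd9 (−0.72) and Hoxa9 (−0.36) were not called in the authors' deposited table. Among 12 noradrenergic and enteric neuron genes, Dbh (−1.67) and Ret (−1.25) were called lower in the authors' deposited table, with 4 lower when adjusted over the list alone. The other way went 5 of the 12, none called, such as Gfra3 (0.69), Gfra2 (0.61) and Chrna3 (0.48) in the authors' deposited table, and the list was drawn up after some of the falls were seen. The list's median of −0.44 lay 0.84 below that of further neuronal genes, which decides nothing about these neurons, since the first list was chosen with its falls known and the second without called genes.

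Of 30 tested forkhead genes with a numeric fold change, 9 were called lower (30%), against 0.315% of other genes. Foxe1, called without a numeric fold change, is not among the 30. The family was picked after these falls were seen, so Fisher's exact test (p = 1.12e-15) restates them and is no independent evidence. Foxi2 (−1.63) was among the 9 and Foxa3 (1.57) was the 1 called higher in the authors' deposited table, and 6 of the 9 were on the mesodermal list fixed beforehand. Neighbours were named tested genes directly next to each other on a chromosome, with a gap of at most 100000 bp. In 16 pairs both neighbours were called higher, against a mean of 2.60 and a maximum of 11 in 10000 permutations (permutation p = 1e-04, the smallest they can give). Many pairs are gene families or liver genes, such as Alb with Afp, Fga with Fgb and Hoxb8 with Hoxb7. Among genes called lower there was 1 such pair, Fendrr with Foxf1, too few to decide (permuted maximum 3, permutation test, p = 0.141). Called genes with an uncalled gene between them, such as Foxf1 with Foxl1 and Foxq1 with Foxf2, were not counted. The count of pairs therefore does not measure how closely the falls lie.

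Of 29 cardiomyocyte genes 16 were called higher in Shh KO, and the list's median was 1.06. The deposited values were not shifted as a whole, since the median of all named tested genes was 0.025. How Cuffdiff scaled the libraries to each other is not given. Such scaling can itself hold this median near 0, so a change in total RNA could not be seen this way. A lower share of the main cell type would raise markers of all other cells alike. Yet the list exceeded endothelial and erythroid markers by 1.08 (permutation test, p = 2e-05, adjusted p = 6e-05). These comparison lists were picked with their values known, while macrophage (median 1.01) and epicardial (0.46) markers did rise. The test thus speaks only against an even rise of all other cells, and an uneven one stays open. More heart tissue in the Shh KO dissections stays open: 1 of 29 members, Gja5, lay at or under the median of all genes. The folds were uneven (interquartile range 0.775), but members may differ in level outside the heart, so this does not count against more heart tissue. Earlier differentiation of progenitors without Shh, which the genotype design gives, also stays open and was untested, since both would raise these genes.

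Hepatoblast genes were higher by a median of 1.77, with Afp at 325 FPKM in Shh KO in the authors' deposited table. They exceeded endothelial and erythroid markers by 1.78 (permutation test, p = 0.00018, adjusted p = 0.00027). This speaks only against an even rise of all other cells, with the same limits as for cardiomyocyte genes. Liver tissue in the Shh KO dissections is a candidate explanation: 11 further tested hepatic genes, none of them in the shorter table, had a median of 0.82 (percentile 99.95), with 7 higher when adjusted over the list alone. All 7 hepatoblast markers are in the shorter table, none is on another list, and Afp was already at 95.6 FPKM in Shh WT, so the tissue as dissected held such transcripts in both genotypes. An effect of genotype on the position or size of the liver bud stays open and was untested.

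Part of the Hox genes and of the neuronal genes were higher in Shh KO. Trunk neural tissue in the Shh KO dissections is a candidate explanation. The 20 further neuronal genes tested, all outside the shorter table, had a median of 0.40 (percentile 99.95), with 18 positive. Of these 20, 6 had an unadjusted Cuffdiff p under 0.05, and none could be called, as the shorter table holds the called genes. Adjusted over the list alone, 2 were higher, Stmn3 (0.96) and Runx1 (0.94), and Runx1 is not specific to neurons. Tubb3 stood at 66.7 FPKM and Stmn2 at 10.9 FPKM in Shh KO in the authors' deposited table. The lists fixed beforehand leave trunk neural tissue open, since neural tube markers had a median of −0.03 (percentile 17.7) and neural crest markers one of 0.05. Of 10 neural tube markers, 6 were tested and 4 were not. The tested ones went both ways in the authors' deposited table (Nkx6-1 −1.67, the 1 called member, Sox2 −0.10, Irx3 0.04, Neurog2 −0.12, Pax6 0.89, Sox3 1.59). Nkx6-1 may depend on Shh itself, so its fall does not count against such tissue. Whole trunk tissue cannot be told apart from no such tissue by sclerotome genes (median −0.29), because these depend on Shh themselves. Loss of Shh in the embryo at large may change where the pSHF border was found, which the labels do not address.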
